A study of Mus musculus with 24 samples.

How the data were processed

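Single-embryo RNA-seq was measured in 24 mouse embryos of the ICR strain, made by in vitro fertilization. Late two-cell embryos were taken into biopsy medium and their blastomeres were parted by micromanipulation. Each blastomere was then grown alone in a modified sodium hyaluronate gel, which gave a pair of sister embryos per two-cell embryo. Control embryos were left intact. Libraries were made with Smart-seq2, which primes cDNA on the poly(A) tail with oligo(dT). The labels gave 4 control 8-cell embryos, 5 control morulae, 3 control blastocysts, 6 split morulae (3 sister pairs) and 6 split blastocysts (3 sister pairs). They gave the pair and the blastomere of each split embryo, but no batch, no litter and no sex.

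The submitters' processing notes named FastQC, MultiQC, cutadapt, HISAT2, featureCounts, edgeR and the genome build GRCm39, without versions. The annotation release and the strand setting were not stated, so counts of overlapping and antisense transcripts (Kcnq1ot1 among them) are uncertain. The deposited count table held raw read counts of 37229 gene symbols, of which 13375 had a count of 0 in all embryos. The deposited TPM table held TPM values (transcripts scaled to a fixed total) of 15625 genes, computed by the authors, and each of these genes had at least 10 counts in at least 3 libraries. Counts of near-identical genes (Eno1 and Eno1b, Pgam1 and Pgam2, Rps2, Trim43b and Trim43c, Obox6, ribosomal protein genes with processed copies) depend on how reads with several matches were counted, which was not stated. The libraries carried no molecular identifiers, so intervals and floors cover counting error only. No 2 count columns were copies of each other.

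Both sisters of a pair come from the same two-cell embryo, so their counts were summed, and each sum stood for 1 embryo. This gave 18 units in 5 groups. Genes were kept by edgeR's filterByExpr on the groups (15875 of 37229), scaled by the trimmed mean of M values, and tested with edgeR's quasi-likelihood F test (robust) in 1 fit of the 5 groups with 13 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The 6 comparisons were control morula against control 8-cell, control blastocyst against control morula, split against control at each of these later stages, split blastocyst against split morula, and the difference between the split effects of the 2 stages. Adjusted p-values are edgeR's unless another tool is named, and all these tests are two-sided. Levels are normalised read counts as CPM (counts scaled to a fixed total per library), given as mean ± SD over units, and log2 fold changes are given ± their standard error. Replicate origins are not stated in the labels, so p-values measure the spread between these units. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

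The groups, the tests, the alternatives, the gene lists, the panel and the rule for naming genes were fixed before the data were examined. The named genes of a comparison were called genes whose units did not overlap between the groups, with a mean log2 CPM of at least 3 and a symbol of a named gene. Among these, the 10 largest changes in each direction were taken for the split against control comparisons, and 6 or 4 for the others. For the difference between split effects, overlap was allowed. A panel of 20 lineage and stage genes and up to 4 members of each list that passed its test were added. Where all units of a group had 0 counts, the fold is a lower bound against a floor of 3 counts at the median library total.

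A set of 28 gene lists was tested with limma's camera on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The lists were trophectoderm, epiblast and pluripotency, primitive endoderm, two-cell stage and genome activation, maternal oocyte transcripts, cell junction and cavitation, Hippo pathway and YAP targets, p53 targets, apoptosis, integrated and unfolded protein stress response, heat shock, oxidative stress response, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded proteins, cholesterol and fatty acid synthesis, cytosolic ribosomal proteins, ribosome biogenesis, DNA replication and G1/S, mitosis and G2/M, imprinted genes, DNA methylation and chromatin regulators, and hyaluronan binding and turnover. Lists of cells and genes that samples could also carry were cumulus and granulosa cells, sperm and spermatids, blood and immune cells, fibroblasts and feeder cells, and Y-linked genes. Each call is given with its adjusted p under an estimated correlation, and counts of members are given over all tested genes and adjusted over the list alone. The rotation test fry asked whether the members of a list moved, on balance, in 1 direction, and did not compare them with other genes.

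Distances between embryos were 1 minus Pearson's r of log2 CPM (prior count 2) and were compared by exact permutation of labels or pairings. Developmental position was the mean log2 CPM of the 200 genes most raised minus the 200 most lowered between a pair of control stages, scaled to 0 and 1 at these stages. Lineage balance was the difference of mean log2 CPM between lineage lists. Relative gene length was recovered from the ratio of deposited counts to deposited TPM. Alternatives were other size factors, DESeq2, other filters, thinning to equal depth, limma on log2(TPM + 1), the replicate number as a block, covariates for detected genes and for Y-linked genes, 1 sister per pair, each split embryo as its own sample, limma-voom with the embryo of origin as a random effect, only the compared groups in the fit, and leaving out each unit in turn. Alternatives chosen after seeing the data took the trend with gene length out of each unit, or left out single units from the list tests. On simulated data of this size, 4-fold changes were called for 18% of genes between split and control morulae and for 19% between split and control blastocysts, and for 34% and 36.5% of genes with a log2 CPM of at least 3. Changes of 2-fold were called for 3% and 2% of genes. Each simulated comparison changed 100 genes at each fold, so these shares need not hold where many more genes change. Gel culture, biopsy medium and manipulation are described for split embryos, and how far controls shared the medium or the gel is left open by the protocol, so their effects were not separated from the splitting itself. Some genes that the naming rule picked are not reported here.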

Results

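RNA of 24 single mouse embryos was sequenced after Smart-seq2. There were 4 control 8-cell embryos with 26.3 to 38.5 M counted reads, 5 control morulae with 13.9 to 19 M and 3 control blastocysts with 11.3 to 12.6 M. Split embryos, each grown from 1 blastomere of a two-cell embryo, comprised 6 morulae (14.2 to 18.8 M) and 6 blastocysts (13.4 to 25.2 M), and at each stage these formed 3 sister pairs. At equal depth, 10994 ± 588 genes were detected in split morulae and 12795 ± 322 in control morulae (SD over embryos). The split blastocysts had 13271 ± 733 genes and the control blastocysts 14627 ± 784. Mitochondrially encoded transcripts made up 2.59% ± 0.504 of counts in split morulae against 3.99% ± 0.852 in control morulae, and 1.69% ± 0.572 in split blastocysts against 4.2% ± 0.691 in control blastocysts.

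The first question was which transcripts changed as control embryos passed from the 8-cell stage (n = 4) to the morula (n = 5). Gata3, a trophectoderm transcription factor, rose from 5.5 ± 4.09 to 210 ± 54.6 CPM (log2 5.25 ± 0.57, adjusted p = 3.57e-06), and the keratin genes Krt8 and Krt18 rose by log2 5.79 ± 1.16 and 5.23 ± 0.61. Lrp2, an endocytic receptor, rose from 1.39 ± 2.33 to 186 ± 24.4 CPM, and Sdc4, a heparan sulfate proteoglycan, from 0.749 ± 1.5 to 252 ± 51 CPM (adjusted p = 0.000154). Rap2b, Akr1b8 and Elf3 were further large rises. Nanog, a pluripotency factor, rose from 40.2 ± 33.4 to 329 ± 53 CPM (adjusted p = 0.00425). Sox2 was at least 19.4-fold higher, at 2.26 ± 1.69 CPM against 0.

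Among the falling genes, Ep300, a histone acetyltransferase, went from 199 ± 37.7 to 11.8 ± 5.26 CPM (log2 -4.08 ± 0.34, adjusted p = 2.58e-08). Arl3, a small GTPase of cilia, went from 130 ± 19.9 to 4.02 ± 2.48 CPM. Chic1, Trim43c, Usp29 and Exoc3l2 fell by log2 values between -4.34 and -4.13. Dppa3, a maternal factor that protects DNA methylation, fell from 23900 ± 5290 to 11500 ± 933 CPM (adjusted p = 3.22e-05). In the panel, Klf2, Tead4 and Gata4 also fell, and Fgf4 and Cdkn1a rose, though the calls of Gata4, Fgf4 and Cdkn1a ended in 8, 8 and 7 of 17 alternatives. Cdx2 (1.47 ± 1.53 against 0.509 ± 1.02 CPM), Eomes, Pou5f1, Tfap2c, Gata6, Pdgfra, Cdh1 and Xist did not pass the test, and Sox17 had no counts in either group.

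In all, 2267 genes rose and 1693 fell, with a median called change of 3.87-fold. Of 27 measured maternal oocyte transcripts, 10 fell and 1 rose (the same counts adjusted over the list alone, list adjusted p = 2.68e-06, adjusted p = 0.00668 with an estimated correlation). Nlrp14 was at least 137-fold lower and Rfpl4 fell by log2 -8.73, while Khdc3, a member of the subcortical maternal complex, rose by log2 3.93 ± 0.38. The median change of these members was -2.88, or -2.11 with genes lacking counts in a group set at their bound. Of 21 oxidative stress genes, 14 rose and none fell (14 and 0 adjusted over the list alone, list adjusted p = 1.53e-07, adjusted p = 0.00668 with an estimated correlation). Sod1, which removes superoxide, rose from 180 ± 31.2 to 1480 ± 192 CPM, Sod2 and Prdx2 rose by log2 2.04 and 2.06, and Hmox1 was at least 207-fold higher. These were the only lists of this comparison that passed with an estimated correlation.

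With the preset correlation alone, 10 further lists passed between 8-cell embryos and morulae. Of 26 trophectoderm genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone, list adjusted p = 0.0144, adjusted p = 0.0959 with an estimated correlation), Dppa1 among them at log2 9.51. Of 29 junction and cavitation genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone, list adjusted p = 0.00764, adjusted p = 0.39 with an estimated correlation), among them Cgn (15.5 ± 16.3 to 276 ± 88.2 CPM), a tight junction protein, and Aqp3, a water channel (7.65 ± 12.4 to 253 ± 66.7 CPM). Cholesterol and fatty acid synthesis had 14 of 32 members rise and 1 fall, adjusted over all genes and adjusted over the list alone, with Insig1, Sc5d and Pmvk among the rises (list adjusted p = 0.00462, adjusted p = 0.39 with an estimated correlation). Of 18 heat shock genes, 9 rose in both counts, Hsp90aa1 and Hspa8 among them (list adjusted p = 0.00698, adjusted p = 0.092 with an estimated correlation). Of 31 glycolysis genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with Eno1, Hk2 and Pgam1 rising (list adjusted p = 0.0216, adjusted p = 0.092 with an estimated correlation). Of 95 nuclear oxidative phosphorylation genes, 39 rose and 8 fell (43 and 12 adjusted over the list alone), and Uqcrc1 rose by log2 2.22 (list adjusted p = 0.0122, adjusted p = 0.512 with an estimated correlation).

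Further lists passed in the falling direction. Of 13 mitochondrially encoded genes, 12 fell and 1 rose in both counts, with mt-Co2, mt-Nd4 and mt-Nd5 at log2 -2.96, -1.32 and -1.22 (list adjusted p = 5.89e-09, adjusted p = 0.0959 with an estimated correlation). Their joint share of counts was 4.37% ± 0.958 in 8-cell embryos and 3.99% ± 0.852 in control morulae (SD over embryos). The falls of most members thus came without a matching fall of their total. Of 83 cytosolic ribosomal protein genes, 53 fell and 6 rose (57 and 6 adjusted over the list alone), with Rpl37a, Rpl38 and Rps21 among the falls (list adjusted p = 5.16e-23, adjusted p = 0.092 with an estimated correlation). Of 35 ribosome biogenesis genes, 17 fell and 1 rose (20 and 2 adjusted over the list alone), with Ddx21, Gnl3 and Ncl falling and Nop56 rising (list adjusted p = 1.53e-07, adjusted p = 0.0631 with an estimated correlation). Of 37 mitosis genes, 13 fell and 8 rose (16 and 9 adjusted over the list alone). Cenpe, Prc1 and Ccna2 fell, and Bub3, a checkpoint protein, rose (list adjusted p = 0.0146, adjusted p = 0.164 with an estimated correlation).

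Control blastocysts (n = 3) were then compared with control morulae (n = 5). Gata3 reached 754 ± 257 CPM (log2 1.84 ± 0.48, adjusted p = 0.0189), and Eomes, a trophoblast stem cell factor, rose from 2.65 ± 3.75 to 56.3 ± 14.1 CPM (adjusted p = 0.0193). Sox2, a factor of the inner cell mass, rose from 2.26 ± 1.69 to 30.4 ± 11.3 CPM (adjusted p = 0.0389). Pdpn, a membrane glycoprotein, rose from 24.4 ± 17.5 to 480 ± 101 CPM, Hnrnpa0, an RNA-binding protein, from 24 ± 8.7 to 348 ± 61.5 CPM (adjusted p = 7.38e-08), and Id2 from 56.9 ± 38.3 to 741 ± 123 CPM. Wipf1, Tln2 and Cdkn1b were the other large rises. The homeobox gene Obox6 fell from 623 ± 154 to 1.9 ± 2.31 CPM, Trim43b from 362 ± 70.5 to 1.64 ± 0.961 CPM and Sox15 from 179 ± 22.7 to 5.42 ± 0.933 CPM (adjusted p = 6.06e-09). Allc, Cfap43 and Tmigd1 fell by log2 values between -5.86 and -4.58. Of 16 alternatives, 9 ended the call of Id2, 9 that of Cfap43, 8 that of Sox2 and 6 that of Eomes. Dppa3 fell to 3170 ± 592 CPM and Cdkn1a, a cell cycle inhibitor, to 19.8 ± 3.08 CPM. Cdx2 (16.4 ± 3.37 against 1.47 ± 1.53 CPM, adjusted p = 0.173), Krt18 (824 ± 302 against 262 ± 102 CPM, adjusted p = 0.0545), Nanog (185 ± 32.5 against 329 ± 53 CPM) and Pdgfra (26.5 ± 14.4 against 1.25 ± 2.12 CPM) did not pass.

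**Figure D1:**
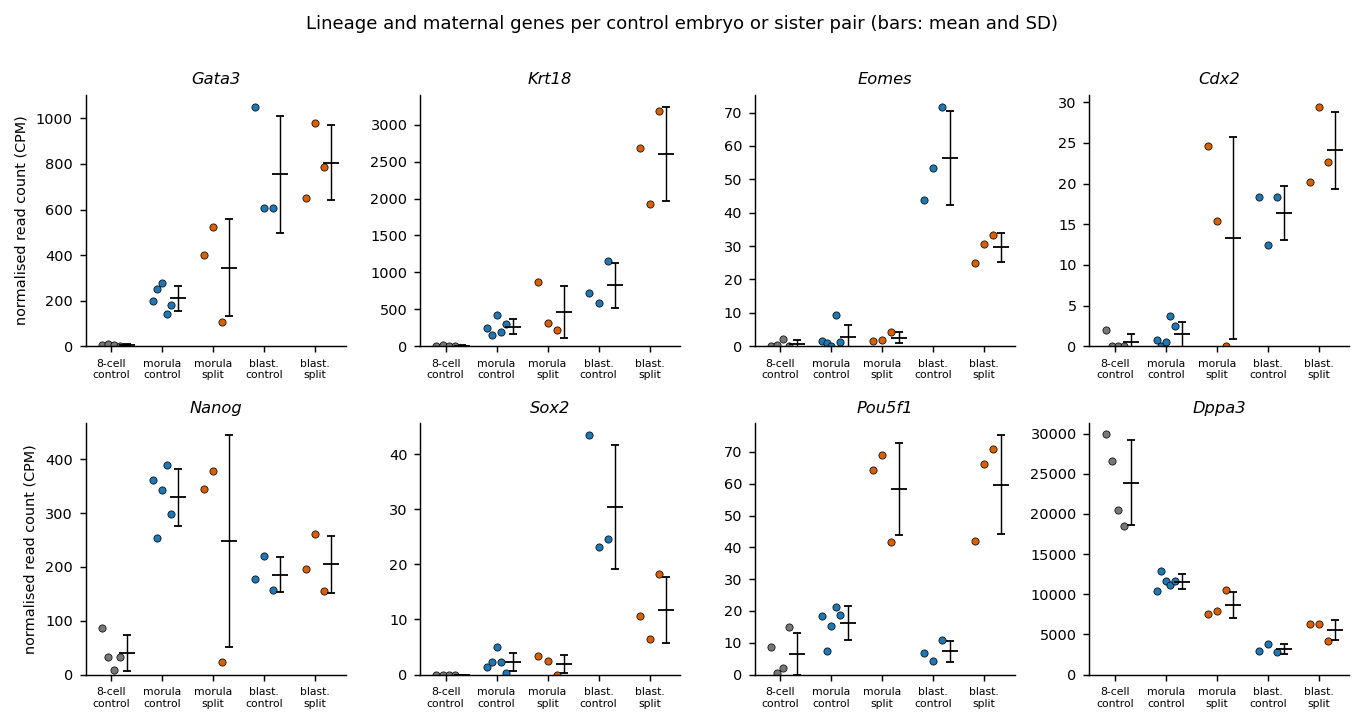
Normalised read counts (CPM, linear axes from 0) of 8 lineage and maternal genes, 1 point per control embryo or summed sister pair, with the mean and SD of each group. Pou5f1 was near 60 CPM in both split groups (58.3 and 59.7) and at 16.2 and 7.32 CPM in control morulae and blastocysts, and split morula pair 3 lay lowest of its group for Gata3, Cdx2 and Nanog.

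Between these stages 496 genes rose and 1184 fell. Of 26 trophectoderm genes, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with Gata2, Tfap2a and Tspan8 rising by log2 10.67, 5.68 and 3.04 and Cd9 falling by log2 -1.12. This list alone passed with an estimated correlation (list adjusted p = 5.93e-07, adjusted p = 0.0183 with an estimated correlation). Of 32 cholesterol and fatty acid genes, 13 rose (16 up and 1 down adjusted over the list alone), among them Acly, Scd1, Sqle and Hmgcs1 (list adjusted p = 5.4e-07, adjusted p = 0.145 with an estimated correlation). Of 20 primitive endoderm genes, Sparc and Fgfr1 (a call that ended in 8 of 16 alternatives) rose and Cited1 fell (2 and 1 also adjusted over the list alone, list adjusted p = 0.0384, adjusted p = 0.141 with an estimated correlation). Of 29 junction and cavitation genes, 2 rose and 1, the water channel Aqp9, fell (3 up and 1 down adjusted over the list alone, list adjusted p = 0.00233, adjusted p = 0.28 with an estimated correlation).

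Of 83 ribosomal protein genes, 37 fell and none rose (50 and 2 adjusted over the list alone), Rpl15, Rpl4 and Rps6 among them (list adjusted p = 8.39e-18, adjusted p = 0.141 with an estimated correlation). Of 35 ribosome biogenesis genes, 11 fell (16 down and 3 up adjusted over the list alone), Nhp2 and Pno1 among them (list adjusted p = 5.04e-05, adjusted p = 0.141 with an estimated correlation). Of 10 two-cell stage genes, Obox6 and Pramel7 fell (4 adjusted over the list alone, list adjusted p = 0.00472, adjusted p = 0.0624 with an estimated correlation). Of 18 heat shock genes, 6 fell, Hspa8 and Stip1 among them, with a list median of -0.48 that was 0.05 on the TPM scale (8 down and 1 up adjusted over the list alone, list adjusted p = 0.0384, adjusted p = 0.145 with an estimated correlation). DNA replication had 11 of 35 members fall and 2 rise (13 and 5 adjusted over the list alone), with Tyms, Slbp and Tk1 falling and a median of -0.22 that was 0.09 on the TPM scale (list adjusted p = 0.0125, adjusted p = 0.145 with an estimated correlation). Mitosis had 12 of 37 fall and 4 rise (15 and 5 adjusted over the list alone), with Ccnb1 and Cdk1 falling by log2 -2.33 and -1.94 and a median of -0.38 that was 0.09 on the TPM scale (list adjusted p = 0.0176, adjusted p = 0.177 with an estimated correlation). On the TPM scale the median of all genes was 0.44.

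The share of rising genes between control morulae and blastocysts was 29.5%, against 41.5% of 2775 genes with DESeq2 and 75.9% of 3565 genes with limma on TPM. Without control blastocyst 1 the count was 1083, and without control blastocyst 3 it was 1095.

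The central question was how embryos grown from 1 blastomere differ from intact embryos of the same stage. At the morula (3 sister pairs against 5 controls), 11 genes rose and 9 fell. Poldip3, an RNA export factor, rose from 95 ± 11.6 to 323 ± 38.3 CPM (log2 1.76 ± 0.2, adjusted p = 0.000332), and Mrm3, a mitochondrial rRNA methyltransferase, from 59.3 ± 12.1 to 162 ± 8.36 CPM (adjusted p = 0.0156). Rdm1, Slc3a2 (an amino acid transporter chain), Nrbp1, Sdad1, Kif22 (a mitotic kinesin), Adrm1 (a ubiquitin receptor of the proteasome), Cndp2 and Alppl2 (an alkaline phosphatase) rose by log2 values from 2.5 down to 0.86. Rap1b, a small GTPase of cell adhesion, fell from 554 ± 49.5 to 173 ± 54 CPM (log2 -1.68 ± 0.21, adjusted p = 0.000773). Nsmce4a, a subunit of a DNA repair complex, fell from 413 ± 97 to 137 ± 41 CPM (adjusted p = 0.00206), and Crls1, the cardiolipin synthase of mitochondria, from 86.9 ± 13.3 to 31.8 ± 1.46 CPM (adjusted p = 0.00942). Ptges3, a co-chaperone of Hsp90, fell from 3080 ± 672 to 1320 ± 392 CPM, and Ppp2ca, Anapc10, Rpl5 and Smarca5, a chromatin remodeller, fell by log2 values from -1.21 to -0.84. Calls ended in 13 of 23 alternatives for Alppl2 and Slc3a2, in 12 for Cndp2, Nrbp1 and Smarca5, in 10 for Adrm1 and Kif22, in 8 for Anapc10 and in none for Rap1b.

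No panel gene was called between split and control morulae. Pou5f1, the pluripotency factor Oct4, was at 58.3 ± 14.6 against 16.2 ± 5.31 CPM (adjusted p = 0.227), Cdx2 at 13.3 ± 12.4 against 1.47 ± 1.53 CPM (adjusted p = 0.344), Gata3 at 344 ± 213 against 210 ± 54.6 CPM, Nanog at 249 ± 197 against 329 ± 53 CPM and Dppa3 at 8690 ± 1590 against 11500 ± 933 CPM. Krt8, Krt18, Tfap2c, Tead4, Klf2, Fgf4, Gata6, Eomes, Sox2, Pdgfra, Cdkn1a, Xist and Cdh1 did not pass either, and Gata4 and Sox17 had 0 counts in split morulae.

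Of the 28 lists, 7 passed at the morula with the preset correlation, and none did with an estimated one or with fry. The 83 ribosomal protein genes had a median of -0.31, with Rpl5 called and 11 falling adjusted over the list alone (list adjusted p = 1.51e-12, adjusted p = 0.391 with an estimated correlation). Of 95 nuclear oxidative phosphorylation genes, 75 had lower fitted values and none was called, with 2 up and 4 down adjusted over the list alone (list adjusted p = 0.00012, adjusted p = 0.434 with an estimated correlation). Uqcrb was at 306 ± 71.4 against 586 ± 85.5 CPM and Uqcrc1 at 960 ± 92 against 565 ± 98.1 CPM. All 13 mitochondrially encoded genes had lower fitted values, mt-Nd1 at 2580 ± 616 against 4960 ± 869 CPM, with none called and 5 falling adjusted over the list alone (list adjusted p = 0.000594, adjusted p = 0.434 with an estimated correlation). The 29 p53 targets had a median of 1.28, with none called and 1 rising adjusted over the list alone (list adjusted p = 0.000254, adjusted p = 0.434 with an estimated correlation). Among them Ei24 was at 69.4 ± 31.8 against 25.5 ± 12.1 CPM, Aen at 73.1 ± 66.6 against 23.3 ± 13.3 CPM and Cdkn1a at 222 ± 157 against 90.7 ± 45.8 CPM. For ribosome biogenesis, none of 35 was called, and 7 rose and 2 fell adjusted over the list alone, with Nolc1 at 420 ± 112 against 238 ± 36.9 CPM (list adjusted p = 0.00522, adjusted p = 0.419 with an estimated correlation). For heat shock none of 18 was called, and 6 rose and 2 fell adjusted over the list alone, with Hspb1 at 158 ± 184 against 24 ± 11.2 CPM (list adjusted p = 0.0122, adjusted p = 0.391 with an estimated correlation). The trophectoderm list had a median of 0.7 and no call in either count (list adjusted p = 0.035, adjusted p = 0.391 with an estimated correlation). It passed in 5 of 12 alternatives.

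At the morula 2377 genes had an unadjusted p under 0.05, and the count of 20 moved with the setting. DESeq2 called 832 genes, limma-voom with the origin as a random effect 159 (19 up and 140 down), each split embryo as its own sample 191, and only the compared groups in the fit 4. Without split morula pair 1 the count was 51, without pair 2 it was 5 and without pair 3 it was 7, and without control morulae 1, 2 and 3 it was 8, 4 and 4. The share of rising genes was 55%, against 39.8% with DESeq2 and 11.9% with limma-voom, which shifted the median of all genes by -0.36.

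At the blastocyst (3 sister pairs against 3 controls), 543 genes rose and 209 fell in split embryos, with a median called change of 2.52-fold. Fdft1, the enzyme that commits farnesyl units to sterols, rose from 119 ± 49.1 to 887 ± 144 CPM (log2 2.9 ± 0.36, adjusted p = 5.23e-05). Pou5f1 rose from 7.32 ± 3.29 to 59.7 ± 15.5 CPM (log2 3.02 ± 0.78, adjusted p = 0.024). The glycolytic genes Eno1 and Eno1b, whose reads cannot be told apart with certainty, rose by log2 2.8 ± 0.4 and 3.47 ± 0.54. Uqcrc1, a core subunit of respiratory complex III, rose from 284 ± 66.5 to 1320 ± 113 CPM (adjusted p = 1.47e-05). Ccnd3, a G1 cyclin, rose from 20.8 ± 7.76 to 126 ± 48.6 CPM, and Acot8, Clk3, Pgam2, Sf3b4 and Cyba were the other large rises. Of 21 alternatives, 9 ended the call of Ccnd3, 8 that of Acot8, 8 that of Pgam2, 7 that of Pou5f1, 6 that of Clk3, 2 that of Cyba, 1 that of Sf3b4 and none that of Fdft1 or Uqcrc1. Dppa3 rose from 3170 ± 592 to 5570 ± 1220 CPM (log2 0.81 ± 0.19, adjusted p = 0.0129, up to 0.715 with 6 of 21 alternatives ending the call).

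Among the genes lower in split blastocysts, Pdpn fell from 480 ± 101 to 88.6 ± 29.2 CPM (log2 -2.44 ± 0.63, adjusted p = 0.0314). The nuclear noncoding RNA Malat1 fell from 3390 ± 1620 to 806 ± 169 CPM (adjusted p = 0.00218). Kcnq1ot1, an imprinted noncoding RNA, fell from 72.4 ± 7.41 to 15.9 ± 8.37 CPM. Cstf2t and Pcf11, factors of mRNA 3' end formation, fell by log2 -2.54 ± 0.42 and -2.21 ± 0.37. Arid1b and Ubn2, chromatin proteins, and Sh3rf1, Hs2st1 and Yes1 fell by log2 values from -2.27 to -1.98. Of 21 alternatives, 13 ended the call of Hs2st1, 12 that of Arid1b, 10 that of Pdpn (adjusted p up to 0.293), 9 that of Kcnq1ot1 (up to 0.95) and 7 that of Yes1, 3 that of Sh3rf1, 2 that of Ubn2, 1 that of Pcf11 and none that of Malat1 or Cstf2t.

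**Figure D2:**
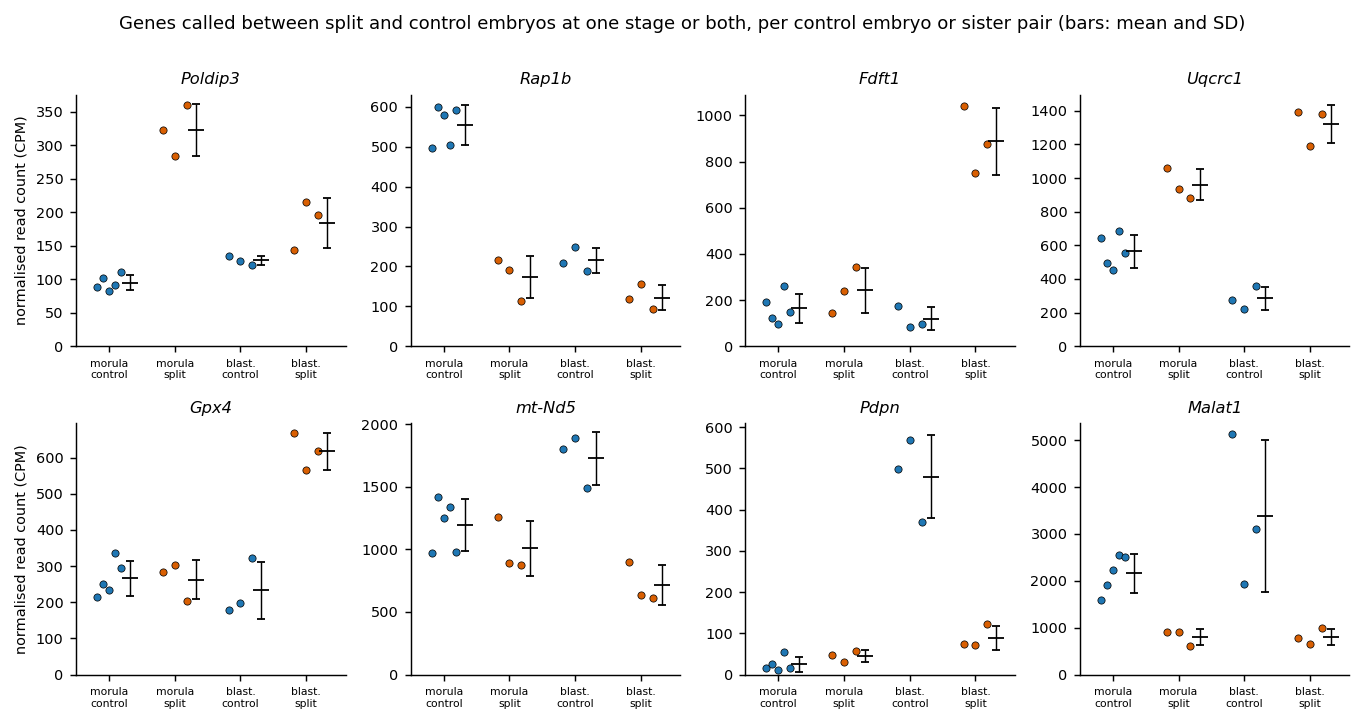
Normalised read counts (CPM, linear axes from 0) of 8 genes in control and split embryos, 1 point per control embryo or summed sister pair, with the mean and SD of each group. Poldip3 and Rap1b were called at the morula, and at the blastocyst Fdft1, Uqcrc1 and Gpx4 rose while mt-Nd5, Pdpn, Malat1 and Rap1b fell.

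The lineage genes of the panel other than Pou5f1 were not called between split and control blastocysts. Cdx2 was at 24.1 ± 4.76 against 16.4 ± 3.37 CPM (adjusted p = 0.981), Gata3 at 806 ± 165 against 754 ± 257 CPM, Eomes at 29.6 ± 4.27 against 56.3 ± 14.1 CPM (adjusted p = 0.895) and Krt18 at 2600 ± 640 against 824 ± 302 CPM (adjusted p = 0.172). Nanog was at 205 ± 52.7 against 185 ± 32.5 CPM, Sox2 at 11.8 ± 6.01 against 30.4 ± 11.3 CPM, Gata6 at 72.1 ± 11.8 against 134 ± 17 CPM and Cdkn1a at 73.9 ± 38.1 against 19.8 ± 3.08 CPM (adjusted p = 0.0512). The lists of trophectoderm (list adjusted p = 0.347), epiblast and pluripotency (0.498, with 4 of 24 members called up) and primitive endoderm (0.779) did not pass. Trophectoderm minus epiblast score was 0.323 ± 0.312 in split and 0.263 ± 0.358 in control blastocysts (exact two-sided permutation p = 1), and primitive endoderm minus epiblast -2.09 ± 0.238 against -1.72 ± 0.166 (exact permutation p = 0.2). With 3 units against 3 the smallest possible p is 0.1. With medians in place of means the difference of the first score turned to -0.964, and it was -0.0117 and -0.0474 without split pairs 1 and 2, and -0.00428 and -0.0784 without control blastocysts 2 and 3.

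Of 13 mitochondrially encoded genes, 8 fell in split blastocysts and none rose (11 and 0 adjusted over the list alone), with mt-Nd5 at 716 ± 160 against 1730 ± 210 CPM and mt-Cytb at 6070 ± 1180 against 15900 ± 4380 CPM (list adjusted p = 1.03e-10, adjusted p = 0.128 with an estimated correlation). Of 32 cholesterol and fatty acid genes, Fdft1, Idi1 and Ebp rose (5 adjusted over the list alone, list adjusted p = 3.17e-07, adjusted p = 0.138 with an estimated correlation). Of 21 oxidative stress genes, 6 rose (8 adjusted over the list alone), with Gpx4, which reduces lipid peroxides, at 617 ± 51.4 against 233 ± 79 CPM and Prdx1 at 2240 ± 168 against 827 ± 155 CPM (list adjusted p = 4.98e-05, adjusted p = 0.0643 with an estimated correlation). Of 35 DNA replication genes, 7 rose (12 adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at 796 ± 89.7 against 340 ± 66 CPM and Tk1, Tyms and Slbp among them (list adjusted p = 0.000302, adjusted p = 0.0937 with an estimated correlation). Of 28 stress response genes of the endoplasmic reticulum and translation, Phgdh, Creld2 and Pdia4 rose (4 adjusted over the list alone, list adjusted p = 0.000435, adjusted p = 0.138 with an estimated correlation). Of 31 glycolysis genes, Eno1, Pgam1 and Bnip3l rose, also adjusted over the list alone (list adjusted p = 0.00128, adjusted p = 0.0643 with an estimated correlation). The call of Pdia4 ended in 7 of 21 alternatives (adjusted p up to 0.372) and that of Bnip3l in 6 (up to 0.177). Of 18 heat shock genes, Ahsa1 and Stip1 rose (5 up and 2 down adjusted over the list alone), with a median of 0.33 and a mean of -0.01 (list adjusted p = 0.0427, adjusted p = 0.214 with an estimated correlation).

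Of 83 ribosomal protein genes, 12 rose (15 adjusted over the list alone), Rpl13, Rpl15 and Rps6 among them, with a median of 0.25 that was 0 on the TPM scale (list adjusted p = 4.46e-05, adjusted p = 0.564 with an estimated correlation). Of 95 oxidative phosphorylation genes, 9 rose (16 up and 1 down adjusted over the list alone), Uqcrc1, Cyc1, Uqcrc2 and Ndufs8 among them, with a median of 0.2 that was -0.07 on the TPM scale (list adjusted p = 0.000435, adjusted p = 0.564 with an estimated correlation). Genes of these lists were short, with median lengths of 0.469 and 0.42 relative to the median of all genes. With the trend of each unit with gene length taken out, their medians were -0.1 and -0.01 and neither list passed (adjusted p = 0.67 and 0.835, the highest of 10 alternatives each, with lowest values of 1.27e-07 and 2.06e-06), nor did heat shock (adjusted p = 0.27, the highest of values from 0.0204). The fall of mitochondrially encoded genes had an adjusted p of 4.42e-14 with the length trend taken out, and cholesterol and fatty acid genes one of 2e-09. The other lists named above passed too, at smaller medians. That of oxidative stress genes went from 0.69 to 0.35 with 2 called, and that of stress response genes from 0.51 to 0.23 with 1 called.

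**Figure D3:**
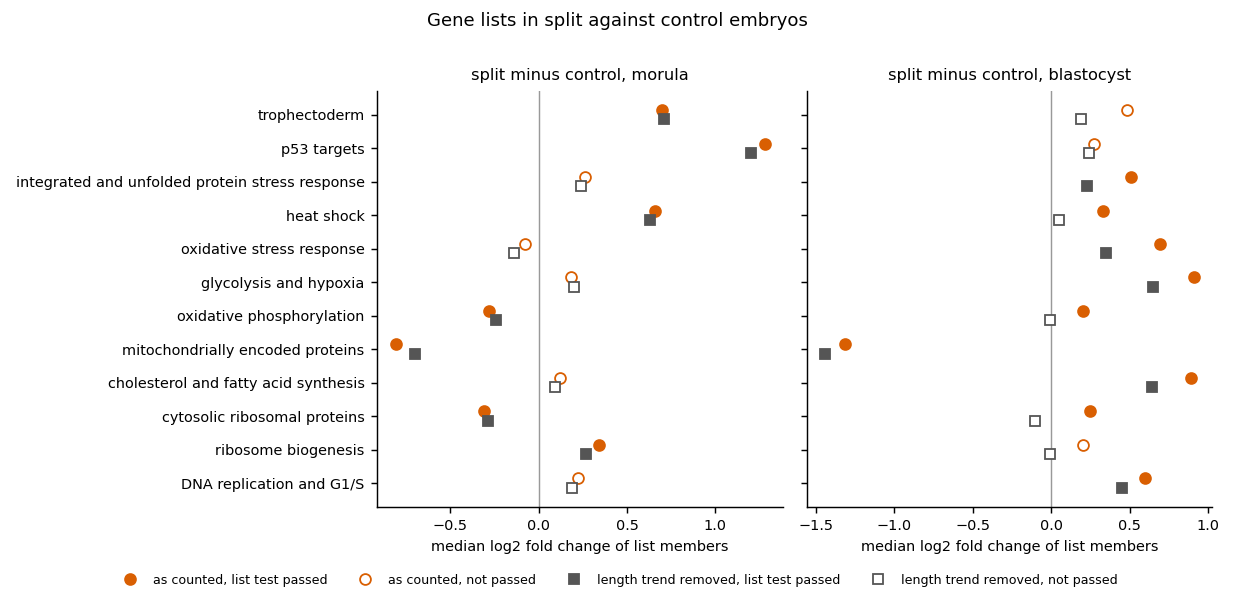
Median log2 fold change of list members, split minus control, at the morula (left) and the blastocyst (right), for lists that passed in either comparison, as counted (circles) and with the trend with gene length taken out (squares). Filled symbols passed the list test at the preset correlation; at the blastocyst, mitochondrially encoded genes stood at -1.31 and -1.44, and ribosomal proteins at 0.25 and -0.1 (0 on the TPM scale).

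Genes lower in split blastocysts were longer than genes higher in them, with median relative lengths of 1.99 and 0.743. With the length trend taken out, 366 genes were called, 332 of them among the 752, and the median size of change of the 752 went from 1.33 to 1.1 on the log2 scale. Kcnq1ot1, Arid1b, Hs2st1, Yes1, Ubn2, Acot8, Pgam2, Pou5f1 and Dppa3 were then no longer called, with Pou5f1 at log2 2.68 and Kcnq1ot1 at -0.44. The share of rising genes was 72.2%, against 40.9% of 946 genes on the TPM scale, where the median of all genes shifted by -0.17, 49.1% of 583 with limma-voom (shift -0.27), 57% of 2037 with only these groups in the fit and 61.4% of 1432 with DESeq2. Without control blastocyst 1 the count was 408 and without control blastocyst 2 it was 463, and without split blastocyst pairs 1 and 3 it was 455 and 445.

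Lists that passed at neither stage included epiblast and pluripotency (adjusted p = 0.875 at the morula), primitive endoderm (0.93), Hippo pathway and YAP targets (0.987 and 0.347), apoptosis (0.443 and 0.498), imprinted genes (0.741 and 0.761), chromatin regulators (0.114 and 0.118) and the 9 measured genes of hyaluronan binding and turnover (0.963 and 0.953). The lists of two-cell stage, maternal oocyte, cell junction and mitosis genes did not pass at either stage, nor did p53 targets at the blastocyst (0.256). Lists of other cells did not pass either, with adjusted p at the morula and the blastocyst of 0.603 and 0.761 for cumulus and granulosa cells, 0.93 and 0.511 for sperm, 0.474 and 0.761 for blood, and 0.93 and 0.761 for fibroblasts. Among their genes Hba-a1 was at 22.8 ± 31.9 CPM in split and 1.76 ± 1.85 CPM in control morulae, Serpine2 at 65.7 ± 77.7 against 18 ± 17.6 CPM, and Cd68 at 19.6 ± 7.1 CPM in split against 5.12 ± 5.82 CPM in control blastocysts. The 8 Y-linked genes had adjusted p of 1 and 0.221, with a median of -1.31 at the blastocyst. Xist exceeded the Y-linked genes in split blastocyst pairs 1 and 3 but only in control blastocyst 3 among the controls of that stage. At the morula it did so in split pair 1 and control morula 5. By this measure the mix of sexes differed between split and control blastocysts.

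Split embryos were next compared between the stages (3 sister pairs each), where 194 genes rose and 468 fell from morula to blastocyst. Lss, a sterol cyclase, rose from 22.2 ± 2.47 to 258 ± 39.3 CPM (adjusted p = 0.00651), and Scd1, a fatty acid desaturase, from 38 ± 28.7 to 390 ± 55.4 CPM. Tuba1a and Camk1 rose by log2 4.71 and 4.56, and Krt18 rose from 469 ± 352 to 2600 ± 640 CPM (adjusted p = 0.0348), though the call of Camk1 ended in 10 of 21 alternatives and those of Tuba1a and Krt18 in 7. Obox6 fell from 961 ± 937 to 8.62 ± 9.63 CPM, and Trim43b, Cux2 and Zfp951 (ended in 7 of 21) by log2 values from -5.06 to -4.5. Pou5f1 was at 58.3 ± 14.6 and 59.7 ± 15.5 CPM (adjusted p = 1), and Eomes at 2.58 ± 1.53 and 29.6 ± 4.27 CPM (adjusted p = 0.176).

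Of 13 lists that passed in split embryos, 6 did so with an estimated correlation. Cholesterol and fatty acid synthesis had 11 of 32 members rise, Idi1, Cyp51 and Fdft1 among them (20 adjusted over the list alone, list adjusted p = 2.22e-18, adjusted p = 0.0118 with an estimated correlation). Oxidative stress genes had 5 of 21 rise, with Txn1, Sod2 and Gpx4 (6 adjusted over the list alone, list adjusted p = 1.13e-05, adjusted p = 0.0118 with an estimated correlation). For the trophectoderm Krt18 and Gata2 rose, with the call of Gata2 ending in 10 of 21 alternatives (adjusted p up to 0.548, 7 up and 2 down adjusted over the list alone, list adjusted p = 1.74e-05, adjusted p = 0.0118 with an estimated correlation). Of 37 mitosis genes, 8 fell, with Cdk1, Cenpe and Ccnb1 (15 adjusted over the list alone, list adjusted p = 2.17e-07, adjusted p = 0.0118 with an estimated correlation). Of 35 ribosome biogenesis genes, 8 fell, with Ddx21 and Nolc1 (12 adjusted over the list alone, list adjusted p = 2.19e-08, adjusted p = 0.0206 with an estimated correlation). Of 10 two-cell stage genes, Obox6 and Pramel7 fell (5 adjusted over the list alone, list adjusted p = 0.000468, adjusted p = 0.0118 with an estimated correlation).

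The other 7 lists passed at the preset correlation alone. Of 95 oxidative phosphorylation genes, 17 rose, Cyc1 and Sdhc among them (36 up and 1 down adjusted over the list alone, list adjusted p = 7.61e-12, adjusted p = 0.0861 with an estimated correlation). Of 29 junction genes, Dsc2, a desmosomal cadherin, was at least 133-fold higher and Aqp9 fell, with the same count adjusted over the list alone (list adjusted p = 0.0207, adjusted p = 0.462 with an estimated correlation). Of 31 glycolysis genes, Eno1 rose and Bnip3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.0236, adjusted p = 0.0563 with an estimated correlation). Of 20 primitive endoderm genes Cited1 fell, also adjusted over the list alone, while the list median was 1.45 (list adjusted p = 0.025, adjusted p = 0.053 with an estimated correlation). Of 28 stress response genes, 4 rose, Hspa5 among them, and 2 fell, Dnajb9 among them at log2 -3.43, with the same counts adjusted over the list alone (list adjusted p = 0.0356, adjusted p = 0.342 with an estimated correlation). Of 18 heat shock genes, 3 fell, with Hspa8 (7 down and 1 up adjusted over the list alone, list adjusted p = 0.0356, adjusted p = 0.15 with an estimated correlation). Of 36 chromatin regulators, 5 fell, with Ezh2 and Kdm5b (9 down and 1 up adjusted over the list alone), at a median of -0.15 and a mean of 0.05, and the median turned to 0.03 on the TPM scale and to 0.09 with limma-voom (list adjusted p = 0.0356, adjusted p = 0.053 with an estimated correlation).

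The count of 662 between split stages was 1865 with DESeq2, 1511 on the TPM scale, 2205 with each embryo as its own sample, 2903 with limma-voom, 413 with only these groups in the fit, 44 with the number of detected genes as a covariate and 1410 with the length trend taken out (131 up and 1279 down, 9.29% rising). The share of rising genes was 29.3% and went to 48.9%, 66.3%, 50.7%, 73.2% and 47.9% under the first 5 of these, with shifts of the median of all genes to 0.19 on the TPM scale and 0.51 with limma-voom. Without split blastocyst pair 3 the count was 292, without pair 1 it was 321 and without split morula pair 3 it was 422.

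The difference between the split effects of the stages was tested gene by gene, and 260 genes differed, 218 of them with a higher effect at the blastocyst. Idi1, an isomerase of sterol synthesis, had a split effect higher by log2 3.01 ± 0.6 at the blastocyst (adjusted p = 0.0109), and Ebp, another enzyme of that pathway, by 2.63. The effect was lower at the blastocyst for Pdpn (-3.31 ± 0.81, adjusted p = 0.0472), Espl1 (the protease separase), Cstf2t and Ankhd1. Of 29 alternatives, 23 ended the call of Pdpn, 22 that of Ankhd1, 12 that of Ebp, 7 that of Espl1 and 3 each those of Idi1 and Cstf2t. Dppa3 differed by 1.22 ± 0.26 (adjusted p = 0.0155, with the call ending in 6). Of 83 ribosomal protein genes, 12 had a higher effect (34 adjusted over the list alone), Rps6 and Rpl15 among them (list adjusted p = 6.59e-16, adjusted p = 0.32 with an estimated correlation). Of 95 oxidative phosphorylation genes, 6 did, Uqcrc2 and Ndufa9 among them (13 adjusted over the list alone, list adjusted p = 2.02e-09, adjusted p = 0.346 with an estimated correlation). Of 21 oxidative stress genes, Prdx1, Sod2, Txn1 and Gpx4 did (6 adjusted over the list alone, list adjusted p = 0.00011, adjusted p = 0.0504 with an estimated correlation). Of 32 cholesterol and fatty acid genes, Idi1, Ebp and Fdft1 did, also adjusted over the list alone (list adjusted p = 0.00593, adjusted p = 0.708 with an estimated correlation). Mitochondrially encoded genes had a lower effect with none called and 2 adjusted over the list alone (list adjusted p = 0.00451, adjusted p = 0.708 with an estimated correlation). With the length trend taken out, no ribosomal protein or oxidative phosphorylation gene was called for the difference. The medians of these lists went from 0.56 to 0.22 and from 0.51 to 0.23, and both lists still passed (list adjusted p = 0.00859 and 0.0174). Chromatin regulators had 2 lower and 1 higher, the lower ones Smarca4 and Chd1 and the higher one Dppa3, with the calls of Chd1 and Smarca4 ending in 15 and 13 of 29 alternatives (4 and 1 adjusted over the list alone, list adjusted p = 0.00702, adjusted p = 0.0504 with an estimated correlation, and 0.0846 with the length trend taken out).

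The count of 260 was 975 with DESeq2, 43 with the length trend taken out, 169 with the replicate block and 125 on the TPM scale, where the share of higher effects went from 83.8% to 39.2%. With DESeq2 that share was 64.9%. Without control blastocyst 1 the count was 108, without control blastocysts 2 and 3 it was 165 and 157, and without split blastocyst pairs 1, 2 and 3 it was 118, 162 and 126. Of the genes called at the blastocyst, 489 of 752 (65%) had the same sign at the morula, while over all 15875 genes Spearman's rho of the split effects was 0.12. Of the 260 genes, 202 had opposite fitted signs at the 2 stages. The genes called at both stages, 10 in number, had the same sign in both. They were Adrm1, Psmd4 (both of the proteasome), Kif22 and Mrm3, which were higher, and Rap1b, Nsmce4a, Crls1, Ptges3, Ppp2ca and Smarca5, which were lower.

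The closeness of whole transcriptomes was then compared. At the morula the mean distance between split and control units was 0.165, with 0.18 within split and 0.144 within control units (excess 0.00292, exact one-sided permutation p = 0.0893 over 56 labellings). At the blastocyst it was 0.133, with 0.0914 and 0.12 within groups (excess 0.0274, exact one-sided permutation p = 0.1, the smallest the design allows). Split units are sums of sister libraries and control units are single libraries, and summing can shrink distances. Between single embryos, split blastocysts that were not sisters were 0.124 apart and control blastocysts 0.115. At the morula these distances were 0.219 and 0.137. With blastomere 1 or 2 alone, the morula excess was 0.00565 and 0.00775 (exact p = 0.0357 and 0.0179), and without split morula pair 1 its exact p was 0.0476. On a course from control 8-cell (0) to control blastocyst (1), split morulae stood at 0.509 ± 0.171 and control morulae at 0.572 ± 0.0389 (exact two-sided permutation p = 0.62). Split morula pair 3 stood at 0.316, and without it the difference turned to 0.0355 (exact p = 0.333). On a course from control 8-cell (0) to control morula (1), split blastocysts stood at 0.949 ± 0.00959 and control blastocysts at 0.916 ± 0.0122 (exact two-sided permutation p = 0.1, the smallest possible). Both groups lay below the control morulae, so the higher score of split blastocysts was the one nearer the morula. The difference of 0.0331 was 0.0547 without control morula 1, 0.0529 without control 8-cell embryo 3 and 0.0222 without control blastocyst 3.

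Sister embryos asked whether embryos from the same two-cell embryo resembled each other. On average, sister morulae were 0.192 apart and other split morulae 0.219, and sister blastocysts were 0.114 apart and others 0.124. Sister blastocysts ranged from 0.0896 to 0.159 and others from 0.0934 to 0.156, so the widest sister pair lay further apart than any others there. Each stage alone gave the smallest exact one-sided p of its 15 pairings, 0.0667, and both together gave a difference of -0.0184 and the smallest of their joint pairings, 0.00444. Without split morula pair 3 that difference was -0.01008. Among split embryos of the same stage, with controls left out, the nearest was the sister for 4 of 6 at each stage, against 20% by chance. Gene by gene, 75 of 10879 tested genes differed between sister pairs of a stage (edgeR, 12 embryos), and 1299 had an unadjusted p under 0.05. Xist, the RNA of the inactive X chromosome, was at 110 and 196 CPM in the sisters of split morula pair 1 and at most at 0.186 CPM in the other pairs of that stage. At the blastocyst it was at 92.6 and 168 CPM in pair 1, at 104 and 115 CPM in pair 3 and at most at 0.0737 CPM in pair 2. Ddx3y and Eif2s3y, on the Y chromosome, had the opposite pattern, and the X-linked homeobox gene Rhox5 was high in the pairs with Xist.

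**Figure D4:**
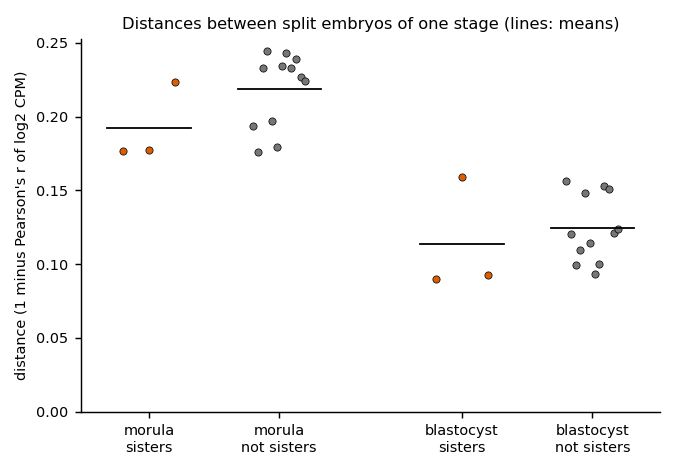
Distances between split embryos of a stage, 1 minus Pearson's r of log2 CPM on an axis from 0, with points for pairs of embryos and lines for means. Sisters averaged 0.192 at the morula and 0.114 at the blastocyst, and embryos that were not sisters 0.219 and 0.124.

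Split morula pair 3 held many of the other genes that differed between pairs. Both its sisters had low levels of the cytoskeletal genes Actg1 (55.5 and 49.7 CPM against 482 to 676 in the other pairs) and Tpm4 (18.1 and 33.9 against 226 to 381), of Cltc, the clathrin heavy chain (58.4 and 77.1 against 305 to 456), and of Vps29. Amot, a Hippo pathway scaffold, had 0 counts in both, against 13.8 to 49.6 CPM. Pttg1ip was at 1060 and 1280 CPM against 312 to 488. Leaving out pairs moved the count of 75 to 14 without split morula pair 3, 21 without pair 1 and 36 without pair 2, and to 31 and 38 without split blastocyst pairs 1 and 3.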

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

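All tests in this part were fixed before their results were seen, apart from the alternatives that take out the trend with gene length, which were chosen after the data were seen. A test for a single embryo far from its group found none in 28 sets of values. Groups of 3 were too small for it, so it covered no control blastocysts and no scores of summed sister pairs. Among single split embryos it cannot see sisters that are off together. Split morula pair 3, whose score was not covered, stood at 0.316 on the course from 8-cell embryo to blastocyst, against 0.637 and 0.576 for the other pairs. What drew attention was the difference between the stages: 260 genes had a split effect that differed between blastocyst and morula. Named genes among them, with the effect at the blastocyst minus the effect at the morula (log2), included Idi1 (3.01), Ebp (2.63), Pdpn (-3.31), Espl1 (-2.86), Cstf2t (-2.62) and Ankhd1 (-2.58). Most alternatives ended the calls of Pdpn (23 of 29, adjusted p up to 0.786) and Ankhd1 (22 of 29), and some those of Ebp (12), Espl1 (7), Idi1 (3) and Cstf2t (3). Of 100 relabellings of the units within their stages, 4 gave as many genes, the real one included, a share under 0.05. The highest of the others called 479. These relabellings broke up the split effect at both stages, and all kept split blastocyst pair 1 as split. They therefore do not test whether the effects of the stages differ. Of the 260 genes, 216 were also called at the blastocyst and 5 at the morula.

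The pattern behind this was that 752 genes were called at the blastocyst and 20 at the morula, although an unadjusted p under 0.05 was reached by 2411 and 2377 genes and DESeq2 called 1432 and 832. A wide spread from split morula pair 3 stays open. Without that pair 7 genes were called at the morula, but leaving out a unit also lowers the power of the test. Unequal depth was argued against, since 746 were called at the blastocyst with all units at the same total. Split blastocysts could lie earlier on the course from morula to blastocyst. On axes built without the control blastocyst being scored, their mean score was 0.668 against 0.874 for the held-out controls, a difference of -0.206. The split pair was lower in 9 of 9 comparisons, but these reused the same 3 pairs and 3 controls. On an axis between earlier control stages, built without any blastocyst, split blastocysts stood at 0.949 and control blastocysts at 0.916. By its scaling control morulae averaged 1 there, so both groups lay below them and split blastocysts lay nearer the morula. A higher score on that axis is therefore no sign of a later stage. The held-out axes rest on the other control blastocysts, so any difference of split from control blastocysts, library properties included, could lower the split score. The held-out score thus cannot tell an earlier place on the course from morula to blastocyst from such a difference. Some genes lay along that course and others did not: Pdpn, which rose from morula to blastocyst in controls, was lower in split blastocysts (a call that ended in 10 of 21 alternatives), and Dppa3, which fell in controls, was higher (ended in 6 of 21, with the length trend taken out among them), but Fdft1, higher by log2 2.9 in split blastocysts, had differed by -0.46 ± 0.3 between control morulae and blastocysts. The length trend was argued against as the whole source of that score, since the difference was -0.167 with the trend taken out. Gel culture, biopsy medium and handling are described for split embryos, and cell number was not measured, so none of these can be told apart from splitting itself.

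The other pattern was length. Genes lower in split blastocysts had a median relative length of 1.99 and genes higher in them 0.743, and among genes that were not called the fold change also fell with length (Spearman's rho -0.177). A length bias of the libraries is a candidate explanation for part of the calls: with the trend taken out, 332 of the 752 genes were still called (44.1%), and the median size of change of the 752 went from 1.33 to 1.1. The calls that ended include Ubn2, from log2 -1.98 to -1.08, and Kcnq1ot1, from -2.19 to -0.44, but also Pou5f1, which went only from 3.02 to 2.68. Control blastocysts carried the trend against the mean control morula, with a lowest rho of 0.151 among them, while split blastocysts had 0.005 to 0.0503. Thus the trend may be a step of development that split embryos lacked or a property of the control blastocyst libraries, and no value here decides between these.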

How the results depend on the processing

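Alternatives that take out the trend with gene length, and list tests without single units, were chosen after the data were seen. The count of genes between control morulae and 8-cell embryos (3960) stayed within 1.5 times under all alternatives run. Each of the 256 called named results kept its sign in all 5077 values of its alternatives, with 667 no longer past the threshold. These results were picked as called in the same data, so a kept sign says little. Lists that passed, 57 results in all, kept their side in 557 of 653 values and failed to pass in 95 with the same direction. In 1 value the direction reversed: ribosomal proteins, up in split blastocysts, were down with the length trend taken out (adjusted p = 0.67). The replicate block gave 3259, 1323, 20, 679, 599 and 169 genes for the 6 comparisons in the order of the report, though the numbers do not pair the embryos. Thinning all units to the same total gave 746 genes at the blastocyst and 37 at the morula. Near-identical gene copies and overlapping genes remained uncertain, and without molecular identifiers duplicate reads were counted as reads.

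With DESeq2 the counts were 2775 between control morulae and blastocysts, 832 between split and control morulae, 1432 between split and control blastocysts, 1865 between split stages and 975 for the difference of split effects. On the TPM scale these were 3565, 35, 946, 1511 and 125. With only the compared groups in the fit, the last 4 were 4, 2037, 413 and 392, and with each split embryo as its own sample they were 191, 816, 2205 and 391, a setting that counts sisters as independent. With limma-voom and the origin as a random effect, 159 genes were called at the morula and 2903 between split stages. With the number of detected genes as a covariate these counts were 69 and 44. With the length trend taken out, 5 genes were called at the morula, 366 at the blastocyst, 1410 between split stages and 43 for the difference. The cause was not tested for these. Leaving groups out of the fit leaves fewer units to estimate the spread, yet the counts at the blastocyst and for the difference rose in that setting.

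The 20 genes at the morula were 69 with no filter, 39 with a filter at 10 CPM, 37 with thinned counts, 131 with blastomere 2 alone and a median of 4.5 over 10 choices of 3 control morulae, so that count rests on the setting. Blastomere 1 alone gave 132 genes for the difference of split effects. The distance of split from control morulae was 0.005654 and 0.007747 with blastomere 1 or 2 alone (exact p = 0.0357 and 0.0179). With medians over members, the difference in lineage balance at the blastocyst was -0.9644. The cause was not tested.

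Leaving out each unit in turn gave 1083 to 1524 genes between control morulae and blastocysts, with the lowest value without control blastocyst 1. It gave 4 (without control morula 2) to 51 (without split morula pair 1) at the morula, and 408 (without control blastocyst 1) to 552 at the blastocyst. Between split stages it gave 292 (without split blastocyst pair 3) to 632, for the difference of split effects 108 (without control blastocyst 1) to 2.3e+02 (rounded), and for genes differing between sister pairs 14 (without split morula pair 3) to 60. The distance of split from control morulae ranged from 0.00146 to 0.005609 (without split morula pair 1, exact p = 0.0476). The difference in position at the morula ranged from -0.1332 to 0.03546, reversed without split morula pair 3, and that in lineage balance from -0.07838 (reversed, without control blastocyst 3) to 0.2624. The difference in position at the blastocyst ranged from 0.02222 (without control blastocyst 3, exact p = 0.4) to 0.05471 (without control morula 1).

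With an estimated correlation the number of lists that passed went from 12 to 2 for control morulae against 8-cell embryos, from 10 to 1 for control blastocysts against morulae, from 7 to 0 at the split morula, from 9 to 0 at the split blastocyst, from 13 to 6 between split stages and from 6 to 0 for the difference. With fry the numbers were 19, 16 and 0 for the first 3 of these.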

Other observations

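Tests in this part were fixed before their results were seen, apart from the alternatives that take out the trend with gene length, which were chosen after the data were seen. Genes that changed with splitting at both stages numbered 10, and all had the same sign; both counts come from 1 fit with shared dispersions, so genes of low spread are called more easily at both stages. At the morula the call ended in none of 23 alternatives for Rap1b, in 1 for Nsmce4a, 2 for Crls1, 6 for Mrm3, 7 for Ptges3, 10 each for Adrm1, Kif22 and Ppp2ca and 12 for Smarca5 (Psmd4 was not followed through the alternatives), and leaving out 1 unit moved the morula count of 20 to between 4 (without control morula 2) and 51 (without split morula pair 1). Adrm1, a ubiquitin receptor of the proteasome, rose by log2 1.02 at the morula and 2.18 at the blastocyst, and Psmd4, another ubiquitin receptor, by 0.76 and 1.37. Kif22, a kinesin of the metaphase plate, rose by 1.27 and 1.42, and Mrm3, which methylates mitochondrial rRNA, by 1.45 and 1.44. Crls1, which makes the mitochondrial lipid cardiolipin, fell by 1.45 and 1.3, Nsmce4a by 1.6 and 1.28, Rap1b by 1.68 and 0.83, and Ptges3 by 1.23 and 1.49. The catalytic subunit of protein phosphatase 2A, Ppp2ca, fell by 1.21 and 1.33, and Smarca5, the motor of ISWI chromatin remodelling, by 0.84 and 1.48.

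In split blastocysts Uqcrc1, Uqcrc2 and Cyc1 of complex III rose by log2 2.21, 1.53 and 1.51, while mt-Cytb, the mitochondrially encoded subunit of the same complex, fell by 1.39. These genes were put together after their values were seen and were not tested as a set, and the other nuclear subunits on the oxidative phosphorylation list were not called: Uqcrfs1 (0.6), Uqcrh (0.1), Uqcrb (0.09), Uqcrq (0.01), Uqcr11 (-0.21) and Uqcr10 (-0.23). All 13 mitochondrially encoded genes had lower fitted values at both stages, and with the length trend taken out their list had an adjusted p of 4.42e-14 at the blastocyst, against 1.03e-10 before (adjusted p = 0.128 with an estimated correlation). The nuclear list, with 9 of 95 genes called up, did not pass in that setting (adjusted p = 0.835) or with an estimated correlation (adjusted p = 0.564). Pou5f1 was at 58.3 ± 14.6 CPM in split morulae and at 59.7 ± 15.5 CPM in split blastocysts, against 16.2 ± 5.31 and 7.32 ± 3.29 CPM in controls, and its call at the blastocyst ended with the length trend taken out (log2 3.02 to 2.68). At the morula Malat1, chosen after its values were seen, was lower by log2 1.42 (adjusted p = 0.0938), and it fell by 2.07 at the blastocyst.

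Rhox5, an X-linked homeobox gene known from extraembryonic tissue, was found in the split embryos that held Xist, which led to the hypothesis that at these stages its transcript is held by embryos with more Xist than Y-linked transcript. In the 8 control morulae and blastocysts, none of which had been used to find it, Rhox5 was above 10 CPM exactly where Xist exceeded the Y-linked genes in 8 of 8. Control morula 5 and control blastocyst 3 had 128 and 108 CPM of Rhox5, and the highest other control of these stages had 6.2 CPM. The values suggest that Rhox5 followed the sex of the embryo here, and a larger series of sexed embryos could test it. Expression from the paternal X chromosome alone is a candidate explanation that was not tested.

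The likeness of sisters was weighed against 2 simple explanations. Shared sex stays open: without Xist and the Y-linked genes the exact one-sided p was 0.00444, but this is the smallest these pairings can give, it was reached with those genes too, and other sex-linked genes such as Rhox5 stayed in. Without split morula pair 3 sisters were still closer, by -0.01008 against -0.0184 with it. This value averages both stages, and its blastocyst part (-0.01051) holds no morula pair and could not change. With pair 3 the morula part was -0.02627. Without it the mean of both stages was smaller in size than the blastocyst part, so the morula part was smaller than -0.01051 in size. Much of the morula part of the likeness of sisters thus went with that pair. Shared time of collection and handling of a pair were not tested, so shared sex, a shared clutch or a shared origin may each lie behind it. Of 100 other ways to pair the embryos, the real one included, 1 gave as many genes differing between pairs as the real pairing (75), and the highest of the others gave 42.

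Other splits of the same samples were counted for each comparison. For control morulae against 8-cell embryos, 1 of 100 splits, the real one, called as many genes (3960, highest other 1290). For control blastocysts against morulae it was 1 of 56 (1680, highest other 1), so the share was under 0.05 for both. For split against control morulae 1 of 56 splits called as many (20, highest other 2), also a share under 0.05. Of the other splits, 11 called genes too, and the count of 20 moved with the setting. For split against control blastocysts (752, highest other 1) and for split blastocysts against split morulae (662, highest other 1), 10 splits are too few for a share under 0.05.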
